A study of [Candida] boidinii with 12 samples.

How the data were processed

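Messenger RNA levels were measured by RNA sequencing in 12 libraries of the methylotrophic yeast Candida boidinii. Per the labels, a wild-type strain and the derived strain LA001-14 were each sampled after 6 h in YPD medium with 2% (w/v) glucose or YPM medium with 2% (w/v) methanol, with 3 biological replicates in each of the 4 groups. LA001-14 carries a lactate dehydrogenase cassette and a kanamycin resistance cassette at random chromosomal positions of the wild type, per the labels. Total RNA was extracted with Trizol and cleaned on columns with DNase treatment, per the labels' protocols. The method of messenger RNA enrichment and the strand setting are not given in the sources used here.

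Each deposited file holds one library with a coding length, a raw read count and an FPKM value for 5712 rows, per the file headers. The counts are whole numbers of reads per coding sequence that the authors deposited without normalization. The FPKM values were also made by the authors, and they equalled the count scaled by coding length and by the sum of the count column, to within 2.4e-06 percent, so they carry no correction for library composition. Bowtie2 2.5.4 is listed in the submitters' processing notes. The counting program, genome build and annotation are not given in the sources used here. Of the 5712 rows, 5711 carry an identifier beginning with CB and 1 is named LDH. The files do not pair the CB identifiers with gene names, and no genome or gene name table was used here, so genes are given by identifier, without chromosome, position or function. Coding lengths were whole multiples of 3 in 5701 rows and their median was 1440 bases.

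Total counts per library ranged from 8045977 to 14107813. Every pair of replicates in a group differed by more than counting noise: the chi-square statistic per degree of freedom, over rows with at least 10 reads in the pair, ranged from 4.03 to 32.3, so no pair was taken for 1 library deposited more than once. The labels call the replicates biological but do not say that they came from separate cultures, and p-values measure the spread between these libraries. Intervals and detection limits on reads cover counting error only.

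Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr on the 4 groups, which left 5466 and removed 246, of which 45 had no read in any library. Library sizes were scaled by TMM, a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries with robust empirical Bayes estimates, and 5 contrasts were tested: methanol against glucose in each strain, LA001-14 against wild type in each carbon source, and the difference between the strains' methanol responses (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The common biological coefficient of variation was 0.0938. Levels are given as TMM-scaled CPM, as mean ± SD with n = 3. The standard error of a log2 fold change comes from the replicate spread of log2 CPM with 2 reads added to each count. Where a group had no read, the fold is a lower bound against 3 reads over that group's libraries, and where it had 1 to 3 reads, the ratio of reads summed over each group, scaled by the summed effective library sizes, is given with its 95% exact (Clopper-Pearson) counting interval.

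The test was tried on simulated data made from the real means over all libraries, library sizes and dispersions, with 200 genes changed in a single group. All other genes had the same mean in every group, and no change exceeded 4-fold. The shares below therefore describe data with few changed genes, and need not hold where most genes change. Each share rests on a single random draw of 66 or 67 genes per fold, made anew for each comparison. Differences in these shares between comparisons can therefore come from which genes were drawn. In the simulation of the wild-type methanol comparison, with 5434 genes tested, 58.2% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 3.45% of calls were false. For methanol in LA001-14 (5440 genes tested) the recovered shares were 67.2%, 92.5% and 97.0%, and 3.93% of calls were false. For the strains on glucose (5434 genes) they were 82.1%, 95.5% and 95.5% with 4.21% false, and for the strains on methanol (5429 genes) 76.1%, 94.0% and 97.0% with 5.32% false. In the simulation of the interaction, with 5433 genes tested, the recovered shares were 61.2%, 83.6% and 98.5%, and 0.613% of calls were false.

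Before the data were examined, a rule fixed which genes are named: up to 10 genes (5 for the interaction) with the largest log2 change in each direction among called genes with a mean of at least 50 counts over all libraries and with no overlap between the replicates of the compared groups, with only the first 2 identifiers per direction and comparison printed because they have no names, together with LDH. For the interaction, no overlap meant that every methanol-to-glucose ratio of 1 strain lay above every ratio of the other. The 32 gene lists fixed at the same time could not be used: 2 of them, those for the cassettes and for pyruvate and lactate metabolism, matched LDH alone, and the other 30 matched no row. No list reached the 3 members needed for a test. Gene groups are therefore defined by the wild-type or LA001-14 response, a choice made after the data were seen.

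Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no low-count filter, a filter at a mean of 50 counts, a replicate block, a fit to the compared groups alone, non-robust estimates, a 2-fold threshold on calls and leaving out each library. Scaling by library totals alone and leaving out the 20 most abundant genes were added after the data were seen.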

Results

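RNA sequencing compared a wild-type strain of Candida boidinii with LA001-14, an L-lactic acid-producing strain made from it, in medium with glucose or with methanol. C. boidinii is a yeast that can grow on methanol, and the comparisons ask how each strain's transcripts differ between the carbon sources and how the strains differ on each of them. The media are named YPD and YPM, which by the usual recipe also hold yeast extract and peptone. Each of the 4 groups held 3 libraries. Total counts ranged from 9171196 to 11004278 in wild type on glucose and from 8108911 to 12622896 in wild type on methanol. They ranged from 8045977 to 10350083 in LA001-14 on glucose and from 8346000 to 14107813 in LA001-14 on methanol.

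The introduced lactate dehydrogenase transcript, LDH, separated the strains in all 12 libraries and was far higher on glucose than on methanol in LA001-14. Lactate dehydrogenase converts pyruvate to lactate, and the labels write the cassette as PENO1-BtL-LDH-TTEF2. LDH stood at 7015 ± 385 CPM in LA001-14 on glucose and at 1846 ± 135 CPM on methanol (SD, n = 3 each), so it fell by 1.93 on the log2 scale (SE 0.076, edgeR adjusted p = 2.02e-14). The 3 glucose libraries lay between 6579 and 7307 CPM and the 3 methanol libraries between 1746 and 1999 CPM. As a share of counts, LDH made up 0.781% ± 0.052 of the glucose libraries and 0.197% ± 0.0077 of the methanol libraries. In the authors' FPKM the means were 7822 ± 523 and 1970 ± 77.1. LDH ranked 11 among all rows by mean level on glucose and 68 on methanol. No LDH read was found in 5 of the 6 wild-type libraries, for which a limit of 3 reads corresponds to 0.370 CPM of unscaled counts at the lowest depth. The remaining library, wild type on methanol replicate 3, had 1 read, or 0.0894 CPM of unscaled counts (95% exact interval 0.0023 to 0.498). On glucose LDH was at least 68329-fold higher in LA001-14 than in wild type. The kanamycin resistance cassette was not analysed here.

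**Figure D1:**
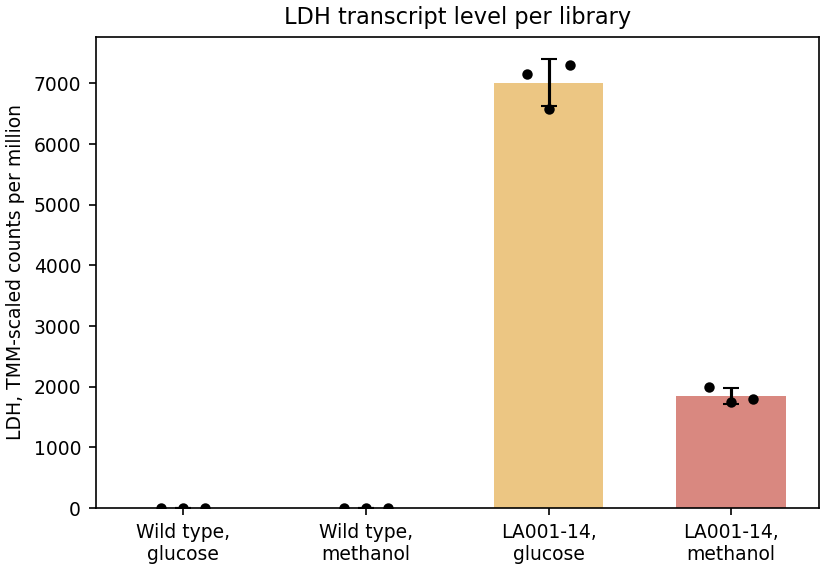
LDH level in TMM-scaled CPM (linear axis from 0) in the 4 groups; bars are means, error bars are SD over 3 libraries and points are single libraries. LA001-14 reached 7015 CPM on glucose and 1846 CPM on methanol, and the wild-type libraries lay at or near 0.

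In wild type, methanol changed the level of most genes, and a small set came to hold a large share of all reads. Of 5466 genes tested, 1913 were higher and 1932 lower on methanol than on glucose, and 718 rose and 839 fell by at least 2-fold. The change was at least 16-fold for 70 genes that rose and 71 that fell. The gene CB2421.t1 (coding length 2121 bases) rose from 0.713 ± 0.626 CPM on glucose to 96288 ± 2974 CPM on methanol, a log2 fold change of 16.95 (SE 0.82, edgeR adjusted p = 3.20e-23). It was the most abundant transcript of each wild-type methanol library, with 8.23% to 8.73% of the counts. CB2420.t1 (3018 bases) had no read in the wild-type glucose libraries and 877 ± 162 CPM on methanol, at least 8678-fold higher (adjusted p = 4.81e-16). CB5361.t1 (1527 bases) stood at 15.8 ± 1.04 CPM on glucose and had no read on methanol, at least 147-fold lower (adjusted p = 3.19e-12). CB3957.t1 (2799 bases) fell from 24.98 ± 2.02 to 0.128 ± 0.143 CPM, a ratio of 232 between reads summed over each group (95% exact counting interval 79.1 to 1129; adjusted p = 1.40e-13). It rests on 3 methanol reads, and the fitted log2 fold change of CB3957.t1 was -8.70 without wild type on methanol replicate 1 and -7.04 without replicate 2.

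The 718 genes that rose at least 2-fold in wild type took 5.46% ± 0.129 of the counts on glucose and 38.4% ± 0.367 on methanol. The 70 genes that rose at least 16-fold took 0.179% ± 0.017 and 21.1% ± 0.365. The 839 genes that fell at least 2-fold went from 38.3% ± 1.67 to 9.88% ± 0.115 of the counts. These groups were chosen on the same wild-type libraries, so their wild-type shares are descriptive. Scaling by the upper quartile or by library totals moved the median change of all genes from -0.0099 to -0.14 and -0.13 on the log2 scale, with 1601 genes higher and 2263 lower by the upper quartile and 1576 and 2197 by library totals. Wild type on glucose replicate 1 stood apart from the other 2 replicates of its group (chi-square per degree of freedom 25.03 and 32.3, against 5.59 between those 2), and without it 1818 genes were higher and 1911 lower.

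LA001-14 also changed most of its genes on methanol, with fewer genes past 2-fold than in wild type. Of the 5466 genes, 1899 were higher and 1624 lower on methanol, while 379 rose and 620 fell by at least 2-fold. The change was at least 16-fold for 19 that rose and 26 that fell. CB4829.t1 (954 bases) rose from 1 read in the 3 glucose libraries to 56.6 ± 6.79 CPM, a ratio of 1738 between reads summed over each group, with a wide 95% exact counting interval of 311 to 68667 (edgeR adjusted p = 1.30e-13). That read lies in LA001-14 on glucose replicate 2, without which the fitted log2 fold change of CB4829.t1 went from 10.29 to 12.14. CB2421.t1 rose from 3 reads over the glucose libraries to 135 ± 24.8 CPM, a ratio of 1397 between summed reads (95% exact counting interval 478 to 6776; adjusted p = 4.97e-17). CB0353.t1 (198 bases) fell from 86.3 ± 6.19 to 1.09 ± 0.198 CPM, and its log2 fold change was -6.28 (SE 0.13, adjusted p = 1.38e-19). CB0769.t1 (741 bases) fell from 1660 ± 120 to 33.9 ± 2.28 CPM, with a log2 fold change of -5.61 (SE 0.082, adjusted p = 3.33e-20). The excess of higher over lower calls depended on the scaling: 1737 were higher and 1742 lower by RLE, 1729 and 1748 by the upper quartile, and 1643 and 1729 by library totals. DESeq2 called 1746 and 1758, and the fit to the LA001-14 libraries alone 1693 and 1796.

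The methanol response differed between the strains for 3206 of the 5466 genes when the difference itself was tested. The response was higher in LA001-14 for 1681 genes and lower for 1525 (edgeR interaction, adjusted p under 0.05). This balance moved with the scaling, to 1601 higher and 1622 lower by RLE, 1849 and 1358 by the upper quartile and 1752 and 1323 by library totals, and DESeq2 called 1616 and 1636. Of the 718 genes that rose at least 2-fold in wild type, 568 (79.1%) had a lower response in LA001-14 and 26 a higher one. Within LA001-14, 394 of the 718 rose, 119 fell and 205 were not called, and 174 rose by at least 2-fold. Their median log2 change was 1.63 in wild type and 0.48 in LA001-14. It was 0.49 in LA001-14 with groups at 0 reads set to the limit of 3 reads. Any gene with 3 reads or fewer in each LA001-14 group was left out of that median. Of the 70 genes that rose at least 16-fold in wild type, 59 had a lower response in LA001-14, 43 rose there and 6 fell. The median log2 change of these 70 in LA001-14 was 1.38. With the same limit and the same rule for leaving genes out it was 1.68. The genes were chosen on wild-type libraries that the interaction also uses, which raises the wild-type median and favours a lower response in LA001-14.

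Genes that fell were also compared by the strain they were chosen on. Of the 839 that fell at least 2-fold in wild type, 541 had a higher (less negative or positive) response in LA001-14 and 62 a lower one. In LA001-14 519 of them fell, 97 rose and 223 were not called. Their median log2 change was -1.54 in wild type and -0.70 in LA001-14. With the choice made on LA001-14 the direction turned: of the 619 genes other than LDH that fell at least 2-fold there, 298 had a lower (more negative) response in LA001-14 and 91 a higher one. The median log2 change of these 619 was -1.45 in LA001-14 and -1.06 in wild type. The 718 genes raised in wild type took 8.14% ± 0.163 of the LA001-14 counts on glucose and 12.3% ± 0.038 on methanol (n = 3 each). The 839 genes lowered in wild type took 32.4% ± 0.477 and 23.03% ± 0.397. The 70 most strongly raised took 0.714% ± 0.0061 and 1.64% ± 0.019. The replicates of the groups did not overlap in these shares, and with 3 libraries against 3 a two-sided exact permutation test cannot give a p below 0.1.

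**Figure D2:**
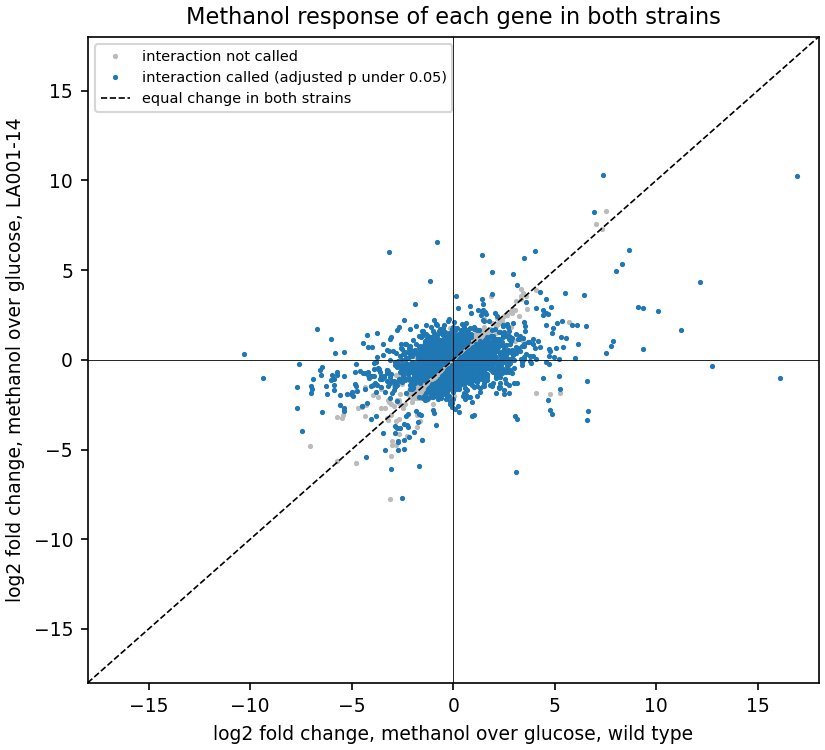
Log2 fold change of each gene on methanol over glucose in wild type (x axis) and LA001-14 (y axis), LDH left out; each point is a gene, blue where the interaction was called and grey where it was not, and the dashed line marks equal change. Most of the 70 genes raised at least 16-fold in wild type lie below the dashed line, and 59 of them had a called lower response in LA001-14.

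**Figure D3:**
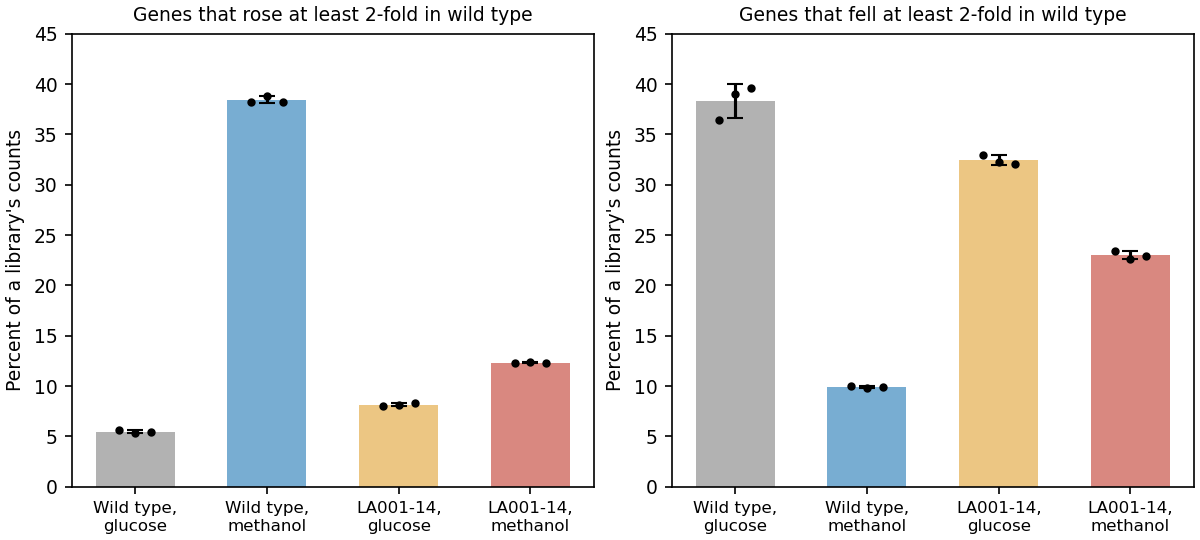
Percent of each library's counts (linear axis from 0) taken by the 718 genes that rose and the 839 that fell at least 2-fold in wild type; bars are means, error bars SD over 3 libraries and points single libraries. The raised genes took 38.4% of the wild-type methanol counts and 12.3% of the LA001-14 methanol counts.

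Single genes showed several forms of this difference. CB5255.t1 (1992 bases) rose from 3.03 ± 0.528 to 21134 ± 1149 CPM in wild type, and in LA001-14 it stood at 8.47 ± 2.37 CPM on glucose and 6.93 ± 0.881 CPM on methanol (interaction log2 -13.09, SE 0.30, adjusted p = 5.15e-22). CB2420.t1 rose in wild type but had only 38 reads over the LA001-14 glucose libraries and 21 over the methanol libraries (interaction adjusted p = 7.10e-10). CB1961.t1 (1116 bases) fell in wild type from 1155 ± 196 to 130 ± 6.34 CPM and rose in LA001-14 from 2.93 ± 0.687 to 188 ± 19.99 CPM (interaction log2 9.17, SE 0.26, adjusted p = 1.08e-19). CB5361.t1, which had no read in wild type on methanol, stood at 7.33 ± 2.35 CPM on glucose and 9.31 ± 1.70 CPM on methanol in LA001-14 (interaction adjusted p = 8.11e-11). CB0353.t1, which fell in LA001-14, rose in wild type from 89.8 ± 14.3 to 768 ± 15.9 CPM. CB0769.t1 fell in wild type from 1729 ± 232 to 33.5 ± 5.26 CPM, and its interaction of 0.085 on the log2 scale did not pass the test (adjusted p = 0.66).

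More genes changed in the same direction in both strains than independent lists would share. Across 5465 genes other than LDH, the log2 changes in both strains correlated with Pearson's r = 0.47 and Spearman's rho = 0.41. This is a correlation across genes, which are not independent replicates, and the 2 comparisons share no library. Of the genes changed at least 2-fold, 174 rose in both strains, where 49.8 would be shared by independent lists, and 320 fell in both, against 95.03. There were 40 genes that rose in wild type and fell in LA001-14, against 81.3, and 36 that fell in wild type and rose in LA001-14, against 58.2. Among the 379 genes that rose at least 2-fold in LA001-14, 210 had a higher response there than in wild type and 78 a lower one, and their median log2 change was 1.37 in LA001-14 and 0.84 in wild type.

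On glucose, LA001-14 already differed from wild type in most genes. Of 5466 genes, 1689 were higher and 1730 lower in LA001-14, and 419 were higher and 467 lower by at least 2-fold. CB5599.t1 (1524 bases) stood at 37.9 ± 4.58 CPM in wild type and 1780 ± 27.0 CPM in LA001-14 (log2 fold change 5.55, SE 0.10, edgeR adjusted p = 2.60e-17). CB2420.t1 had no read in wild type and 1.28 ± 0.331 CPM in LA001-14, at least 12.3-fold higher (adjusted p = 0.000251). CB1961.t1 was lower in LA001-14, at 2.93 ± 0.687 CPM against 1155 ± 196 CPM in wild type (log2 fold change -8.64, SE 0.24, adjusted p = 2.65e-20). CB0874.t1 (1488 bases) stood at 378 ± 90.3 CPM in wild type and 2.52 ± 1.00 CPM in LA001-14 (log2 fold change -7.19, SE 0.39, adjusted p = 1.10e-15). With library totals in place of TMM the median gene moved from 0.012 to 0.23 on the log2 scale, and 2335 genes were called higher and 1168 lower.

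On methanol, 1793 genes were higher and 1799 lower in LA001-14 than in wild type, and 532 were higher and 609 lower by at least 2-fold. CB5255.t1 showed the largest fall by the naming rule, to 6.93 ± 0.881 CPM from 21134 ± 1149 CPM in wild type (log2 fold change -11.59, SE 0.12, edgeR adjusted p = 6.43e-25). CB2420.t1 stood at 0.658 ± 0.460 CPM against 877 ± 162 CPM (log2 fold change -10.42, SE 0.47, adjusted p = 1.03e-15). The LA001-14 value of CB2420.t1 rests on 5, 12 and 4 reads, and without LA001-14 on methanol replicate 2 the log2 fold change was -11.12. CB2566.t1 (1647 bases) was higher in LA001-14, at 10121 ± 341 CPM against 36.3 ± 2.46 CPM (log2 fold change 8.13, SE 0.064, adjusted p = 8.67e-25). On glucose CB2566.t1 stood at 3805 ± 440 CPM in wild type and 3081 ± 170 CPM in LA001-14. CB5361.t1 had 9.31 ± 1.70 CPM in LA001-14 and no read in wild type, at least 84.3-fold higher (adjusted p = 8.21e-11). With library totals in place of TMM the median gene moved from 0.0048 to 0.28, and 2578 genes were called higher and 1127 lower.

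The strain differences on glucose and on methanol were weakly correlated. Across 5465 genes other than LDH, the correlation of the log2 differences was r = 0.20 and rho = 0.23, again across genes. Of genes at least 2-fold different, 94 were higher in LA001-14 on both carbon sources, where independent lists would share 40.6. The same count for lower genes was 127, against 52.0. There were 66 genes higher in LA001-14 on glucose and lower on methanol, against 46.6, and 36 with the opposite order, against 45.4.

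**Figure D4:**
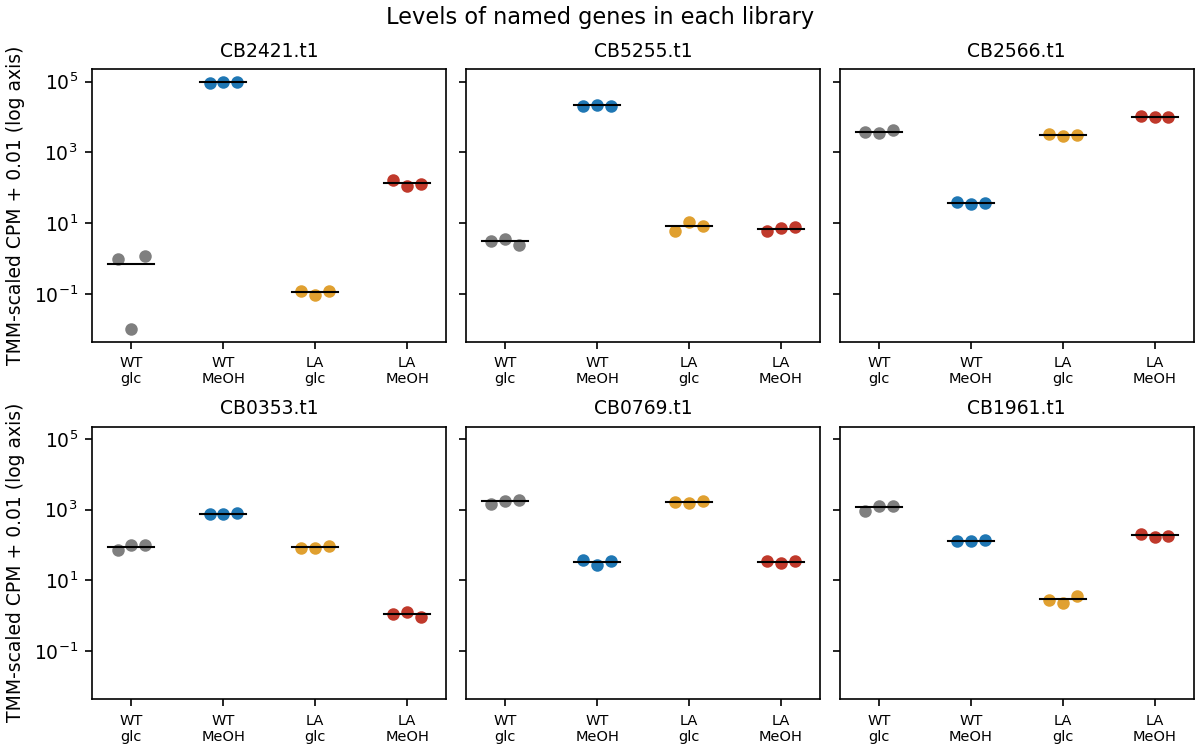
TMM-scaled CPM plus 0.01 (logarithmic axis) of 6 genes named in the text, in wild type (WT) and LA001-14 (LA) on glucose (glc) or methanol (MeOH); points are single libraries and lines are means of 3. CB2421.t1 and CB5255.t1 reached 96288 and 21134 CPM in wild type on methanol and 135 and 6.93 CPM in LA001-14, whereas CB0769.t1 was near 33.5 CPM on methanol in both strains.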

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

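The tests of dilution, of coding length and of a batch shared by a strain, the counts over genes selected on LA001-14, and the spread of the regroupings were added after the results they weigh were seen, and the settings with library totals or without the 20 most abundant genes, and the count of genes raised in wild type with a lower response, after the data were seen.

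The methanol response differed between wild type and LA001-14 by a test of the difference itself, with 1681 genes higher and 1525 lower in LA001-14. Of the genes raised at least 2-fold in wild type 568 had a lower response in LA001-14, and of the genes lowered at least 2-fold 541 had a higher one. The interaction of 4 named genes had adjusted p-values of 8.11e-11 (CB5361.t1), 1.08e-19 (CB1961.t1), 7.10e-10 (CB2420.t1) and 5.15e-22 (CB5255.t1) in edgeR. Among 100 regroupings of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many interaction calls, the real one with 3206; the highest other gave 1886. The regroupings mix strains and carbon sources within groups, and their common biological coefficient of variation was 0.296 to 0.511, against 0.0938 for the real groups, so they do not decide whether chance can be excluded for this count. For the 4 pairwise comparisons the real split of 6 libraries called 3845, 3523, 3419 and 3592 genes (methanol in wild type, methanol in LA001-14, strains on glucose, strains on methanol), and the highest of the other 9 splits called 0 in each. Only 1 of the 10 splits, the real one, was as large in each case, and 10 splits are too few for a share under 0.05. The other splits also mix the compared groups, so the difference itself adds to their spread and few calls could come from them.

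The first pattern is the smaller rise in LA001-14 of genes raised on methanol in wild type. The choice of genes on wild-type libraries favours it. For the 379 genes raised at least 2-fold in LA001-14 it turned round, and 210 had a higher response there and 78 a lower one. That turn was less lopsided than the 568 lower against 26 higher among the 718 genes chosen on wild type. Over all 5466 genes tested, chosen on neither strain, the median absolute log2 change was 0.570 in wild type and 0.465 in LA001-14. Leaving out the 20 most abundant genes did not lessen the pattern. Of the genes raised in wild type, 80.9% then had a lower response, against 79.1% with those 20 kept. The same choice of genes favours both shares, so neither measures the pattern free of that choice. Comparing these shares argues against the 20 transcripts adding to the pattern by taking up reads. Other abundant transcripts were not tested. Another explanation is dilution of the LA001-14 methanol libraries by cells or RNA in the glucose state. If the strains otherwise had equal levels, it would bring each gene to about the same share of its wild-type rise. Of the 70 genes raised at least 16-fold, 18.6% lay within 2-fold of the median share of 3.98%, while 16 showed no rise at all and 7 reached over 50% of it. Dilution alone of a response equal to that of wild type would not give such unequal shares. The strains differed in 3419 genes on glucose, however, so unequal shares can arise with or without dilution, and a part played by it stays undecided. A slower or different course of methanol use at 6 h and an effect of the strain itself stay open and were not tested, so no biological explanation can be singled out.

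The second pattern is the lower LDH level on methanol. Scaling does not account for it: over TMM, RLE, upper-quartile and total-count scaling and without the 20 most abundant genes, the log2 change nearest to 0 was -1.93. Nor did genes at the same level fall in general, since the change of LDH lay at percentile 2 of the 100 genes nearest in level, whose median was 0.18. Lower activity on methanol of the sequence written PENO1 in the cassette is an open hypothesis, because the native gene it came from was not identified here.

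The third pattern is the large difference between the strains on glucose, where 3419 genes were called. The log2 difference correlated with coding length (Spearman's rho 0.19 across genes). The strain difference on methanol had a similar trend (rho 0.20). For methanol over glucose rho was -0.098 in wild type and -0.079 in the derived strain. With each library's length trend removed 3393 genes were called on glucose, so that trend alone does not carry the difference. The wild-type glucose library that stood apart, replicate 1, does not carry it either: 3430 genes were called without it. A batch shared by a strain, or a separate batch or harvest for each group, cannot be told apart from the strains and groups themselves. The length trend found in both strain comparisons does not decide this, since such a batch or the strains themselves could give it. The count with that trend removed does not test other effects of a batch. A called interaction was found for 58.7% of the genes tested. A methanol response of its own in each strain gives that with or without a batch. In addition, the random integration sites, selection of the clone and growth state at 6 h remain open and untested.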

How the results depend on the processing

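Scaling by library totals and leaving out the 20 most abundant genes were alternatives chosen after seeing the data, as was the count of genes raised in wild type with a lower response in LA001-14. All 386 alternative values of the named gene folds kept their direction and call, including LDH in LA001-14, whose log2 change lay between -1.995 and -1.88. Apart from LDH, these genes were chosen for the largest called changes without overlap in the same libraries, which favours that outcome. Of the counts of called genes, those that moved by over 1.5 times did so under a 2-fold threshold, with 1 exception. That threshold left 718 higher and 839 lower genes for methanol in wild type, 379 and 620 for methanol in LA001-14, 419 and 467 for the strains on glucose, 532 and 609 for the strains on methanol, and 685 and 698 for the interaction, because it removes the calls of small size. The exception was scaling by library totals, which left 1127 lower genes between the strains on methanol, because it moves the median gene to 0.28. The count of 568 genes raised in wild type with a lower response in LA001-14 ranged from 480 to 579. Leaving out single libraries gave 1814 to 1833 higher and 1836 to 1911 lower genes for methanol in wild type, and the strain counts on glucose ranged from 1535 to 1841 and from 1589 to 1720. DESeq2 shared between 95.6% and 99.4% of the edgeR calls in the same direction. The replicate numbers did not pair the libraries: same-numbered deviations from the group means correlated at -0.13 to 0.12, and 2 of the 12 libraries correlated best with a library of their own number. With the replicate block 1892 genes were higher and 1915 lower for methanol in wild type, and no count moved by over 1.5 times. The correlation between the strains' methanol responses ranged from 0.45 to 0.47, and that of the strain differences from 0.16 to 0.22, with the filter at a mean of 50 counts and with each library left out, the alternatives run for them. The planned tests of gene lists were not run because no list had 3 identifiable members. Depth limits genes with a few reads: CB4829.t1 in LA001-14 rests on 1 glucose read.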

Other observations

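The test of neighbouring identifiers against random orders and the genes changed at least 16-fold were chosen after the result was seen. On the first principal component of log2 CPM, the LA001-14 methanol libraries lay between 0.932 and 4.93, apart from the wild-type methanol libraries at 65.1 to 66.9. The wild-type glucose libraries lay between -28.7 and -23.7 and the LA001-14 glucose libraries between -44.0 and -40.3. The LA001-14 methanol libraries correlated with wild type on glucose at r = 0.909 to 0.920 and with wild type on methanol at r = 0.887 to 0.898, across genes. Reads were spread over more genes in LA001-14: 50% of the counts lay in 204 ± 15.4 genes on methanol, against 131 ± 3.61 in wild type (SD, n = 3 each).

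Of the 26 genes that fell at least 16-fold on methanol in LA001-14, 24 also fell at least 2-fold in wild type. Of the 19 that rose at least 16-fold there, 16 rose at least 2-fold in wild type. Of genes chosen by the wild-type response, 38 of the 70 genes raised at least 16-fold in wild type rose at least 2-fold in LA001-14, and 41 of the 71 that fell at least 16-fold fell at least 2-fold. Summed over these 71 genes, however, the share of counts in LA001-14 was 1.55% ± 0.046 on glucose and 2.22% ± 0.030 on methanol, against 2.02% ± 0.069 and 0.0444% ± 0.0025 in wild type (SD, n = 3 each). The rise of this summed share in LA001-14 rests on CB2566.t1, which is among the 71. CB2566.t1 stood at 3081 ± 170 CPM on glucose and 10121 ± 341 CPM on methanol in LA001-14. Most of the 71 genes did not rise there: 50 fell and 6 rose, and their median log2 change was -1.47. CB5599.t1 crossed over between the strains. It was higher in LA001-14 on glucose and lower on methanol, at 372 ± 19.5 CPM against 968 ± 210 CPM in wild type.

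Genes with neighbouring identifiers changed alike to a small degree. Spearman's rho between identifiers next to each other was 0.125 for methanol in wild type, and between 0.093 and 0.104 in the other 4 comparisons. Each exceeded the highest of 1000 random orders (one-sided permutation p = 0.001, adjusted 0.001, the smallest they can give). Genes changed at least 4-fold do not alone account for it. Without them rho was 0.1002 for methanol in wild type, and between 0.068 and 0.095 in the other 4 comparisons. Runs of genes with smaller changes were kept, so a part played by those was not tested. One hypothesis is that the identifiers may follow genome order, with neighbours regulated alike. It stays undecided: rho between identifiers 50 apart was at most 0.012 in the pairwise comparisons, but 0.035 in the interaction, which is not small beside the 0.093 of neighbours there, and the order of the identifiers is not stated. CB2420.t1 and CB2421.t1, which both rose on methanol in wild type, are such neighbours.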
